A study of Mus musculus with 13 samples.

How the data were processed

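STAT3 binding was measured by CUT&RUN, in which an antibody (here anti-STAT3, clone 124H6) guides a nuclease to its target in permeabilised cells and the released DNA fragments are sequenced. Per the labels, mouse splenic B cells were cultured for 96 h with anti-CD40 (1 µg/mL) and IL-4 (12.5 ng/mL), sorted into IgM+ and IgG1+ cells, and 400000 sorted cells were stimulated for 1 h with anti-CD40 and either IL-4 (12.5 ng/mL) or IL-21 (10 ng/mL). The series has 13 samples. The 12 antibody libraries fall into 8 groups: 4 wild-type (WT) groups with 2 libraries each and 4 STAT3 knockout (KO) groups with 1 library each. The input sample was not analysed here. The labels do not say whether replicates came from separate animals, so p-values of tests over libraries measure only the spread between these libraries, which may be technical. Fisher's exact tests that count genes or regions take those as units, and their p-values do not measure that spread. The KO genotype was taken from the labels, since a peak list holds no measure of the deleted gene.

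The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.4.1, MACS2 2.2.7.1, deepTools 3.5.1 and the mouse genome build mm10, without saying which did what. The labels also record 1 pg of yeast spike-in DNA and 14 PCR cycles. The use of the spike-in, the control for peak calling and any filter of reads or regions are not given in the sources used here. Each library has its own deposited peak list. Each deposited list gives a position, a summit, a fold enrichment (a ratio of the signal at the summit to the local background), a −log10 p, a −log10 q and a score that equals the whole part of 10 times the −log10 p. The lowest −log10 p in the deposited lists was 5.00. Fold enrichments are the authors' own values for each peak, and were used only to describe, rank or filter peaks within a list.

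The 12 lists held 13908 peaks, of which 13513 on chromosomes 1 to 19, X and Y were used and 395 on unplaced sequences or the mitochondrial genome were left out. Peaks of different libraries that overlapped by at least 1 bp were merged into regions, and a library had a region when at least 1 of its peaks lay in it. A region was called gained when it had a peak in all WT IL-21 libraries compared and in no WT IL-4 library compared, and lost in the reverse case. Gained regions were called absent in KO when the KO IL-21 library of the same isotype (both KO IL-21 libraries for the set of both isotypes) had no peak there. Depth is not given with the lists. The fold and −log10 p of a peak together fix a whole fragment pileup and a Poisson background, and a solution within 0.001 was found for 99.0% to 100% of the peaks with a −log10 p under 30 in each library. By this reading, the lowest background was 1.72 to 2.61 fragments per library and the smallest pileup called was 10 to 12 fragments. This is the smallest height called anywhere in a library, and where the local background is higher a larger pileup can go uncalled. The absence of a peak therefore does not mean the absence of binding. No library shared an identical peak record with another.

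Gene names and positions came from a RefSeq gene table on GRCm38.p6, the assembly that mm10 is made from. The table gives the start and end of 21887 protein-coding genes without strand or exons. A planned assignment to the nearest transcription start was therefore replaced by the nearest protein-coding gene span within 50000 bp of the region's best summit, with ties settled by the nearest gene end, and the planned promoter share by the share of peaks with a summit within 1000 bp of either end of a protein-coding gene. Exons and introns are not given for this reason. The planned search for STAT motifs needs the genome sequence and was not run. Positions are 1-based, on mm10.

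Peaks per library were compared on a log2 scale by two-sided exact permutation tests within strata: treatment within isotype and isotype within treatment in WT (36 arrangements, smallest p 0.0556), and genotype within treatment and isotype (81 arrangements, smallest p 0.0123). The treatment and isotype tests cannot reach 0.05. Shares of peaks were tested in the same way, with Benjamini-Hochberg adjustment over the 3 contrasts of a measure. Each WT region was tested by Fisher's exact test on its presence in 4 against 4 libraries, adjusted over 7461 regions, and the count of gained regions was set against all 35 splits of the 8 WT libraries into 4 and 4. Replicate overlap is the share of the peaks of both libraries that overlapped a peak of the other, with chance from 100 circular shifts. Intervals of shares are exact 95% Clopper-Pearson intervals, and cover counting error only. Gene lists were tested by two-sided Fisher's exact tests over the 4631 genes with a region in WT, adjusted over 9 lists: JAK-STAT signalling and feedback, plasma cell differentiation, B cell identity and germinal centre, survival and proliferation, IL-4 and STAT6 responsive genes, immunoglobulin constant regions, markers of T and NK cells, markers of myeloid cells, and housekeeping promoters. The 9 lists hold 192 entries and 185 distinct genes, all of which were matched in the gene table.

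Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the genes nearest to the top 15 regions gained in both isotypes and absent in KO by the mean within-library percentile of −log10 p, the top 5 regions each of those gained in IgM only, gained in IgG1 only, lost, and found in all 12 libraries, and up to 5 genes per list with a gained region. Some regions and list members that this rule names are not reported here. Other regions named in the text are said to be chosen after their values were seen. The region counts were tested on simulated lists made for WT IL-21 against WT IL-4 with 200 known gained sites among 13718 regions. With each site found in 90% of the IL-21 libraries, 59.5% of the sites were recovered in all 4 where 65.6% were expected, with 0 false regions. With 70%, 24.0% of the sites were recovered, equal to the 24.0% expected. The simulated background fell at random and independently in each library, apart from sites common to all, so false regions were nearly impossible by construction. Detection was set equal in the 4 IL-21 libraries, whereas the real ones found 55.3% to 98.2% of the regions found by the other 3. The simulation therefore checks the counting and not the rate of false regions in the real lists. The alternatives covered stricter thresholds, list length, the overlap and merging rules, gene distances, other permutations, a replicate block and leaving out each WT replicate. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.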

Results

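STAT3 binding sites were mapped in IgM+ and IgG1+ B cells that had been activated with anti-CD40 and IL-4 and were then given IL-4 again or IL-21 for 1 h. These were parallel arms, and the labels record no IL-4 in the 1 h with IL-21. Adding IL-21 and leaving out IL-4 therefore cannot be told apart. IL-21 signals through STAT3, whereas IL-4 signals mainly through STAT6, and the STAT3 KO cells serve as a control for the antibody. The WT lists held 1455 and 853 peaks with IL-4 in IgM cells, 651 and 623 with IL-4 in IgG1 cells, 2034 and 1171 with IL-21 in IgM cells, and 865 and 1485 with IL-21 in IgG1 cells. The KO lists held 763 (IL-4, IgM), 1892 (IL-4, IgG1), 1073 (IL-21, IgM) and 648 peaks (IL-21, IgG1). Merging gave 11227 regions, of which 10180 were found in exactly 1 of the 12 libraries.

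The first comparison asked which STAT3 sites appear with IL-21. In WT cells 98 regions had a peak in all 4 IL-21 libraries and in no IL-4 library, and 0 regions showed the reverse. The strongest of them lay at the end of Gen1, a Holliday junction resolvase (chromosome 12, 11265209 to 11266187), with a mean fold enrichment of 21 ± 6.89 (SD, n = 4 libraries of both isotypes). Next came Gsk3a, a kinase of glycogen and Wnt signalling (20.3 ± 3.89, SD, n = 4, 495 bp outside the gene, chromosome 7, 25237427 to 25238731), and Rabggta, a subunit of the Rab prenylation enzyme (20.7 ± 8.49, SD, n = 4, within the gene, chromosome 14, 55721695 to 55722352). A region 13532 bp from Socs3, the feedback inhibitor of STAT3 signalling (chromosome 11, 117951914 to 117953025), had a fold of 18.1 ± 6.47 (SD, n = 4). The region within Il10, which encodes an immunoregulatory cytokine (chromosome 1, 131022698 to 131023418), had a fold of 14.0 ± 4.68 (SD, n = 4).

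The other genes of the top 15 were Ncf1, a subunit of the phagocyte NADPH oxidase, Muc1, Akt2, a kinase downstream of PI3K, Stard3nl, Elmo2, Med29, a Mediator subunit, Crtc2, a coactivator of CREB, Zfp446, Phf6 and Serpinb6a. Their mean folds ran from 11.6 at Serpinb6a to 18.8 at Ncf1. In the real split of the 8 WT libraries 98 regions separated the sides, against at most 8 in the other splits of the 35. Fisher's exact test gave p = 0.0286 for each of the 98 regions, the smallest value that 4 against 4 libraries allow, and 0 regions passed adjustment over the 7461 regions found in WT (smallest adjusted p = 1). Leaving out the first IgG1 IL-21 library raised the count from 98 to 215.

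**Figure D1:**
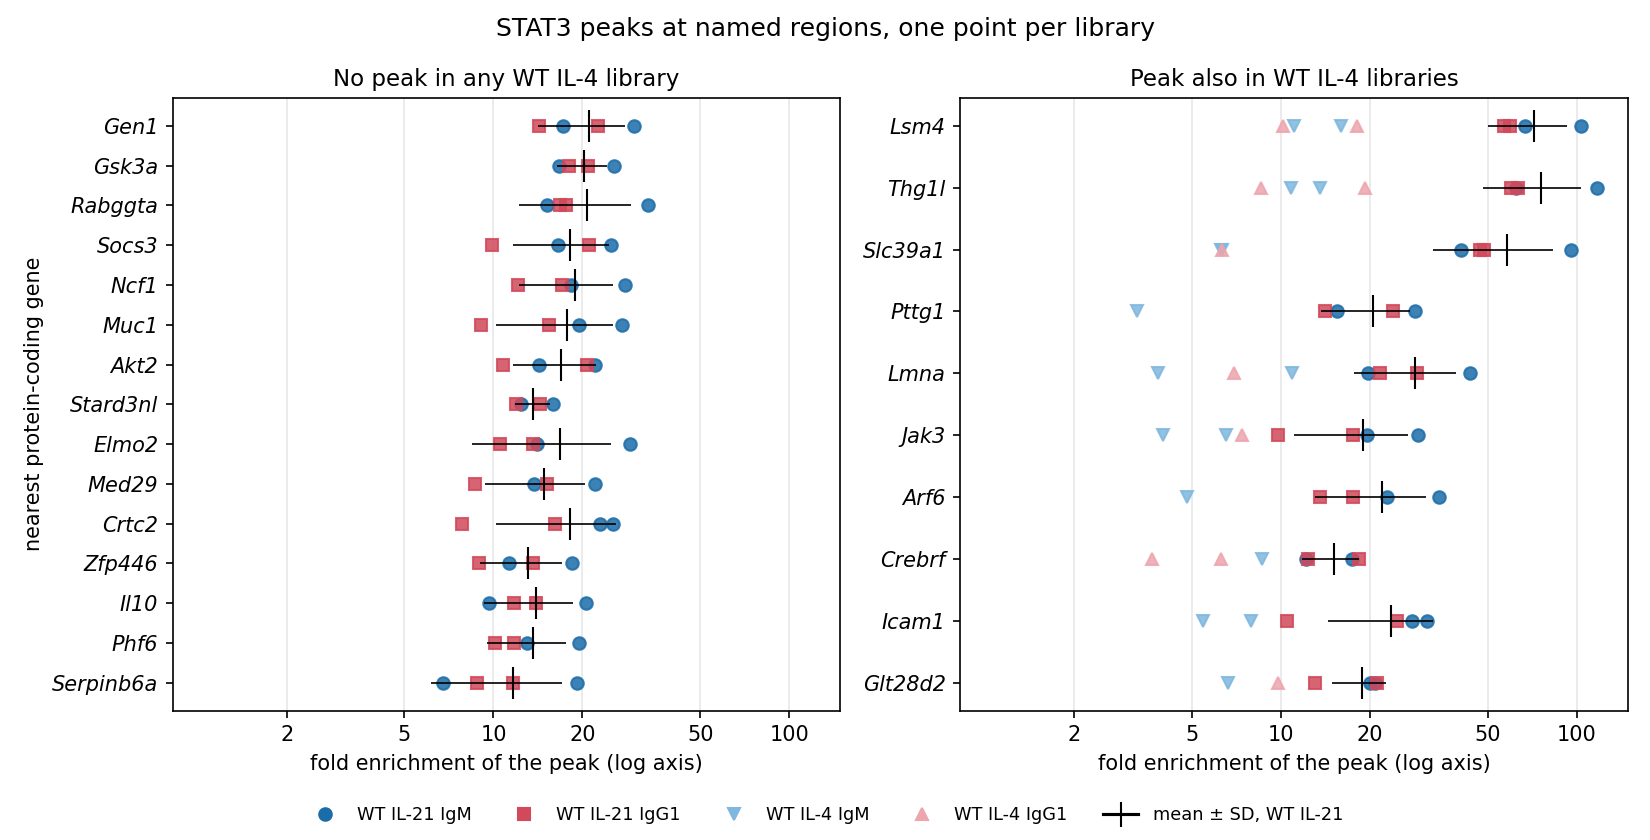
Fold enrichment per library, on a log axis, at the 15 top regions gained with IL-21 (left) and at 10 regions that also had WT IL-4 peaks and no KO peak (right), each named by its nearest protein-coding gene (the region named by Pttg1 lies 61474 bp from it and 15627 bp from Mir146). Points are libraries, bars are the mean ± SD of the 4 WT IL-21 libraries, and the left panel runs from a mean of 11.6 (Serpinb6a) to 21 (Gen1).

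**Figure D2:**
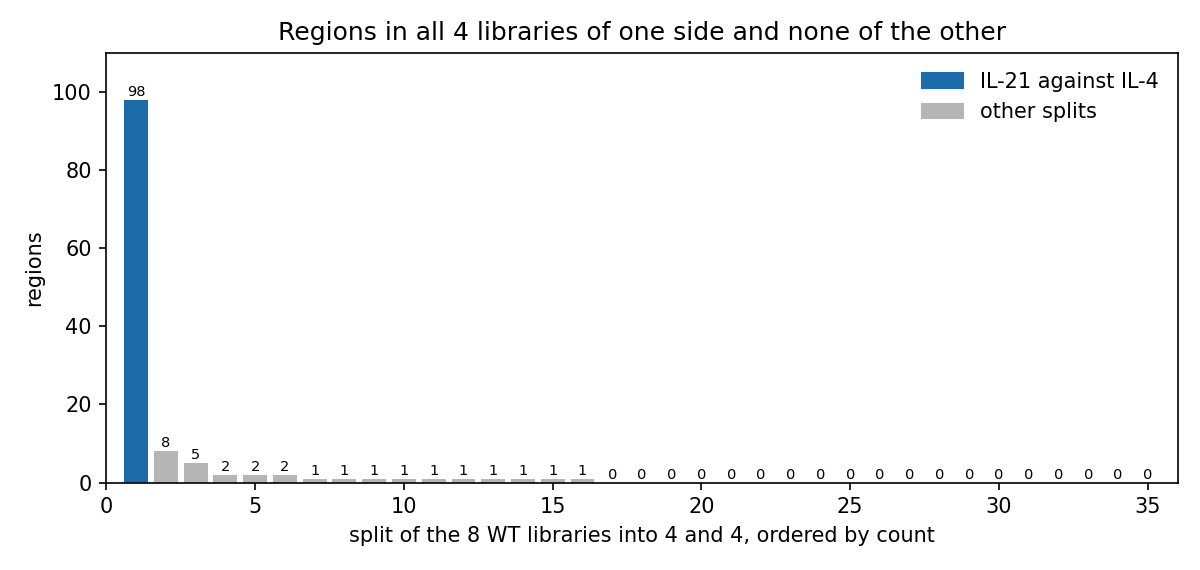
Number of regions (vertical axis) with a peak in all 4 libraries of one side and none of the other, for each of the 35 splits of the 8 WT libraries into 4 and 4 (horizontal axis). The bar for IL-21 against IL-4 stands at 98 and the next at 8.

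Gained sites included regions at Socs3, a feedback gene of JAK-STAT signalling, Bcl6, a germinal centre gene, Bcl3, a survival gene, and Il10. Whether such groups of genes were enriched depended on the background. Against all genes with a region in WT, 5 of the fixed lists held more genes with a gained region than expected. Most background genes rest on regions found in a single library, which cannot be gained. Against the 675 genes with a region in at least 2 WT libraries, a background chosen after seeing the data, no list passed (adjusted p = 0.376 for JAK-STAT genes and for plasma cell genes, and 0.177 for the B cell, survival and IL-4 lists, Fisher's exact test). Of the 19 JAK-STAT signalling and feedback genes with a region in WT, 9 had a region gained in either isotype and absent in KO, where 1.36 were expected (adjusted p = 1.92e-05, Fisher's exact test). Among them were Stat3 itself, the inhibitors Socs1, Socs3 and Cish and the phosphatase Ptpn1. The gained region at Ptpn1 (chromosome 2, 167958973 to 167960164) lay within the gene and had a fold of 9.79 ± 4.83 (SD, n = 4). The region 10444 bp from Cish (chromosome 9, 107313004 to 107313681) was found in 3 of the 4 IL-21 libraries at a mean fold of 9.83. The region 79 bp from Stat3 had a fold of 14.0 ± 6.53 (SD, n = 4) and also a peak in 2 WT IL-4 libraries, and so was not among the 98.

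Socs3 had 6 gained regions, more than any other gene. They lay between 117946243 and 117969687 on chromosome 11, around and within the gene (117966079 to 117970336). The first IgG1 library with IL-21 had a peak in 3 of the 6 regions, and the other 3 IL-21 libraries had one in each. No WT IL-4 or KO library had a peak in the mapped window.

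**Figure D3:**
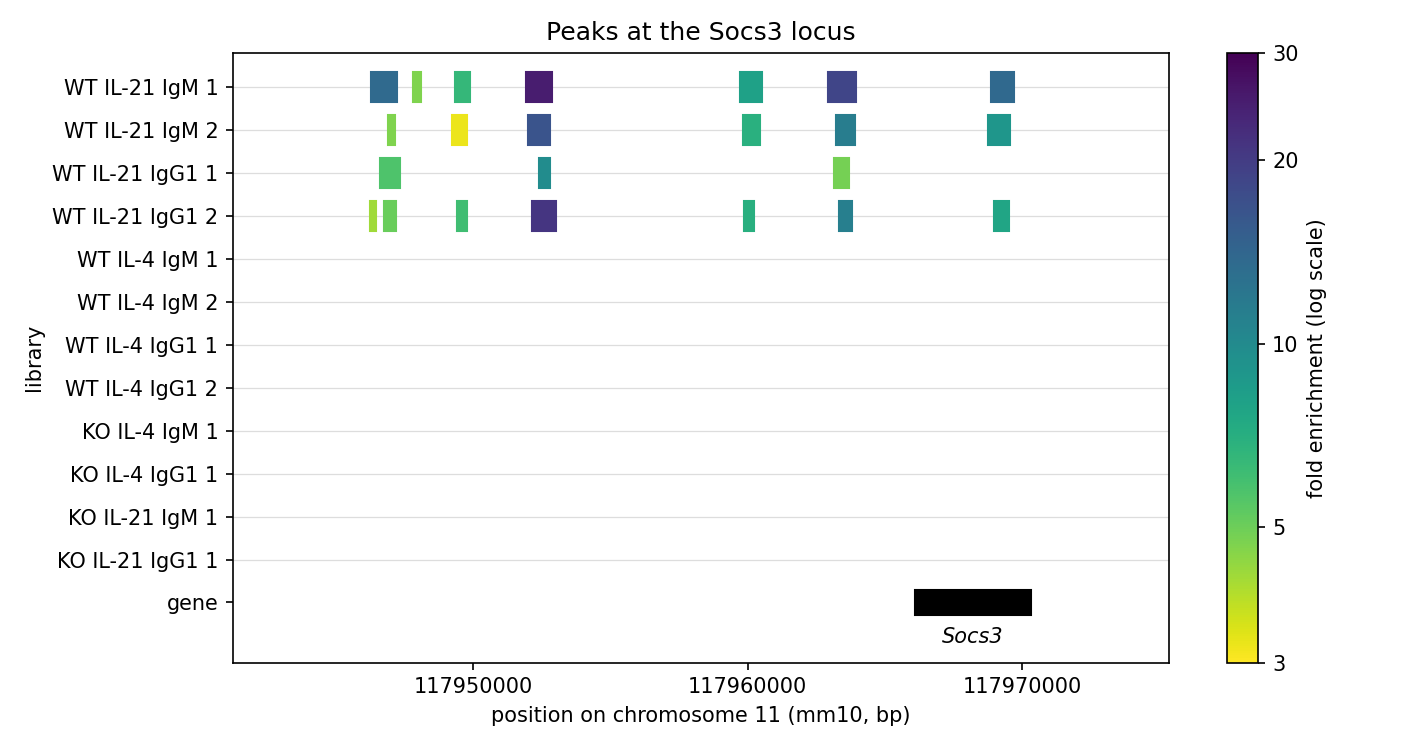
Peaks of the 12 libraries (rows) at Socs3 on chromosome 11 (horizontal axis, mm10, bp), coloured by fold enrichment on a log scale, with the gene span as a black bar below. Peaks in this window appear only in the 4 WT IL-21 libraries, in 6 gained regions between 117946243 and 117969687 and 1 region found in a single library.

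Genes of B cell identity and the germinal centre gave 7 of 19 members (1.36 expected, adjusted p = 0.000638, Fisher's exact test): Bcl11a, Bcl6, Ccr7, Id3, Irf8, Pou2af1 and Tcf4. The region within Bcl6, the master regulator of the germinal centre programme (chromosome 16, 23988392 to 23989110), had a fold of 15.7 ± 9.90 (SD, n = 4). That near Ccr7, a chemokine receptor that guides B cells to the T cell zone, had a fold of 11.8 ± 4.86 (SD, n = 4). Survival and proliferation genes gave 8 of 17 (1.22 expected, adjusted p = 3.87e-05, Fisher's exact test): Bcl2l1, Bcl3, Birc3, Egr1, Klf10, Mcl1, Pmaip1 and Trp53inp1. Bcl2l1 and Mcl1 encode anti-apoptotic proteins, whereas Pmaip1 encodes a pro-apoptotic protein. The Bcl11a, Id3 and Klf10 regions also had a peak in the KO IgM library with IL-4. The region within Bcl3 had a fold of 10.1 ± 4.08 (SD, n = 4), and the gained regions at Mcl1 and Bcl2l1 were each found in 2 IL-21 libraries.

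Plasma cell genes gave 4 of 14 (Batf, Id2, Il10 and Jund, 1.00 expected, adjusted p = 0.0260, Fisher's exact test). The gained regions at Batf and Jund were each found in 3 IL-21 libraries. Both genes also had a region found in 7 WT libraries, 4 with IL-21 and 3 with IL-4, which was not gained. The plasma cell regulators Prdm1 and Irf4 each had 1 region, found in 1 WT library, and 0 gained regions. IL-4 and STAT6 responsive genes gave 4 of 9 (Batf, Bcl2l1, Cish and Ptger4, 0.643 expected, adjusted p = 0.00540, Fisher's exact test). Of these 4, Batf, Bcl2l1 and Cish also stand on other lists. Among markers of other cells, Csf3r alone of 4 myeloid genes had a gained region (0.286 expected, adjusted p = 0.385, Fisher's exact test). The log2 odds ratio of the myeloid list (2.48) was close to that of the plasma cell list (2.49). The T and NK cell list gave 0 of 3 (0.214 expected, adjusted p = 1, Fisher's exact test). The housekeeping list gave 0 of 2 (0.143 expected, adjusted p = 1, Fisher's exact test), and no immunoglobulin constant region gene had a region assigned. Only genes entered as protein-coding could be assigned a region, so this does not show that the immunoglobulin loci lack sites. With so few genes expected, the myeloid, T and NK cell and housekeeping lists cannot show whether enrichment was particular to the other lists. The survival call ended when a region needed a peak in at least 3 of the 4 WT IL-21 libraries and in no WT IL-4 library (adjusted p = 0.102, Fisher's exact test), as did the IL-4 call (adjusted p = 0.120). With the same number of peaks from each list the plasma cell call (adjusted p = 0.367, Fisher's exact test) and the IL-4 call (adjusted p = 0.140) ended. Without 1 of the WT IL-21 libraries, whichever it was, the log2 odds ratio fell from 3.59 to between 2.10 and 2.89 for JAK-STAT genes and from 3.57 to between 2.00 and 2.29 for survival genes. The plasma cell call also ended without either IgG1 IL-21 library or the first IgM IL-21 library, the B cell call without the first IgM IL-21 library (adjusted p = 0.170) and the IL-4 call without the first IgG1 IL-21 library (adjusted p = 0.142, Fisher's exact tests).

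The comparison with KO cells asked which sites had no peak without STAT3. Of the 98 gained regions 97 had no peak in either KO IL-21 library, and 6 (6.12%) had a peak in any KO library. Of all 7461 regions found in WT, 164 had a peak in a KO IL-21 library and 353 (4.73%) in any KO library. Lacking a KO peak was thus the rule for WT regions and does not by itself set the 98 apart. In all, 167 regions had a peak in the 4 WT IL-21 libraries and 125 of these had none in any KO library. The 33 of the 125 that also had WT IL-4 peaks included the peaks with the highest fold in each WT IL-21 library, those at Thg1l and Lsm4. They were chosen after their values were seen, and by −log10 p 4 regions found in all 12 libraries ranked above them. At Thg1l, a tRNA-modifying enzyme (chromosome 11, 45954952 to 45955902), the mean fold was 75.7 ± 27.6 (SD, n = 4) with IL-21 and 13.0 with IL-4, and at Lsm4, an RNA-binding protein of the splicing machinery (chromosome 8, 70673105 to 70674353), 71.5 ± 21.4 (SD, n = 4) and 13.8. Both regions had peaks in all 8 WT libraries and in 0 of 4 KO libraries. Slc39a1, a zinc transporter, had a fold of 57.9 ± 25.2 (SD, n = 4) with IL-21, and Jak3, the kinase of the common gamma chain, 19 ± 7.95 (SD, n = 4). Each of these folds is relative to the background of its own library.

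Among the 6 IL-21 libraries, 139 regions had a peak in the 4 WT libraries and none in the KO pair, while the other 14 choices of a pair gave at most 2. The mean log2 peak number differed by 0.08 between the genotypes (WT minus KO, exact permutation p = 0.938). The 4 KO lists held at most 1 peak each with a fold of at least 10, the WT IL-21 lists 28 to 175 and the WT IL-4 lists 2 to 8, a threshold chosen after the data were seen (WT against KO, exact permutation p = 0.0123, the smallest possible, adjusted p = 0.0370). KO peaks overlapped a mean of 3.78% of WT peaks with IL-21 and 5.98% with IL-4 (difference −2.20 percentage points, exact permutation p = 0.0556, the smallest possible). Among peaks with a −log10 q of at least 5 the difference was −15.1 percentage points, at the same p. Both WT libraries of a group were compared with the same KO library, so these shares rest on 1 KO list per group. Those lists differ in length, and the permutation does not account for this. The 19 regions found in all 12 libraries included 3 near the start of chromosome 9 (between 3000918 and 3025114) and 1 on chromosome 2 (98666585 to 98667302), with mean folds of 1.55 to 1.89 with IL-21 at the top 5 and no protein-coding gene within 100000 bp.

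IgM and IgG1 cells were then compared. In IgM cells 322 regions were gained with IL-21 and 10 lost, and in IgG1 cells 181 were gained and 1 lost. The 98 regions gained in both made up 30.4% of the IgM set and 54.1% of the IgG1 set. Of the 322, 232 had a peak in 1 or 2 IgG1 IL-21 libraries, and of the 181, 169 had one in 1 or 2 IgM IL-21 libraries. Top regions gained in IgM cells alone and absent in KO lay at Rnf44, Mdm2, the ubiquitin ligase of p53, Csf3r, Pou2af1, a B cell coactivator, and Serpinb1c, with mean folds of 9.30 to 11.8 (2 libraries each). Those gained in IgG1 cells alone included regions at Rab20, Cib1, Rbm3 and Id3, an inhibitor of E proteins, at 4.36 to 6.31. Gained alone means here without a peak in the WT IL-21 libraries of the other isotype. In WT IgM cells with IL-4, the Cib1 region had a peak in 1 library (fold 4.53) and the Id3 region in 2 (4.93 and 5.34). The Id3 region also had one in the KO IgM library with IL-4 (fold 5.21). These 2 regions were thus not confined to IgG1 cells.

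With IL-21, 93 regions had a peak in both IgM libraries and neither IgG1 library, and 13 the reverse. Pairing the libraries across isotypes gave 159 and 5 regions in one arrangement and 30 and 30 in the other, so the isotype split was not the largest. Leaving out an IL-21 library leaves its isotype with a single list, and the excess then lay with that isotype: 937 regions of IgG1 only and 103 of IgM only without the first IgG1 library, 594 and 228 without the second, 816 of IgM only and 61 of IgG1 only without the first IgM library, and 1488 and 16 without the second. Of the regions found by the other 3 IL-21 libraries, the first IgG1 library found 55.3% (95% CI 49.5 to 61.0), the second IgM library 77.7% (71.5 to 83.1), the second IgG1 library 94.4% (89.9 to 97.3) and the first IgM library 98.2% (94.9 to 99.6). With 2 libraries per side an exact permutation test cannot pass, and none was made of the isotype difference within a treatment. Leaving out an IL-21 library leaves its group with a single list and raised the per-isotype gained counts to between 802 and 1874. Leaving out an IL-4 library does the same to the lost counts, which then exceeded the gained counts: 773 lost and 355 gained in IgM cells without the first IL-4 library and 1300 and 335 without the second, and 577 and 200 in IgG1 cells without the first and 588 and 186 without the second.

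Replicates resembled each other more with IL-21 than with IL-4. Peaks of the 2 replicates overlapped for 25.6% (95% CI 24.1 to 27.1) of IgM and 19.9% (18.3 to 21.5) of IgG1 peaks with IL-21, against 5.03% (4.17 to 6.0) and 4.95% (3.82 to 6.28) with IL-4 and at most 0.0424% on average after random shifts. Overlap between the isotypes with IL-21 was as high, at a mean of 22.6% (17.8 to 28.8 over 4 pairs of libraries). IL-21 lists were 1.57-fold longer than IL-4 lists on average (log2 difference 0.65, exact permutation p = 0.111) and IgM lists 1.54-fold longer than IgG1 lists (log2 difference 0.63, exact permutation p = 0.111). Neither difference passed, and 0.0556 is the smallest p the design allows. The IL-21 difference reached this p among peaks with a −log10 q of at least 5 (log2 difference 1.82) and among peaks with a fold of at least 5 (1.36).

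**Figure D4:**
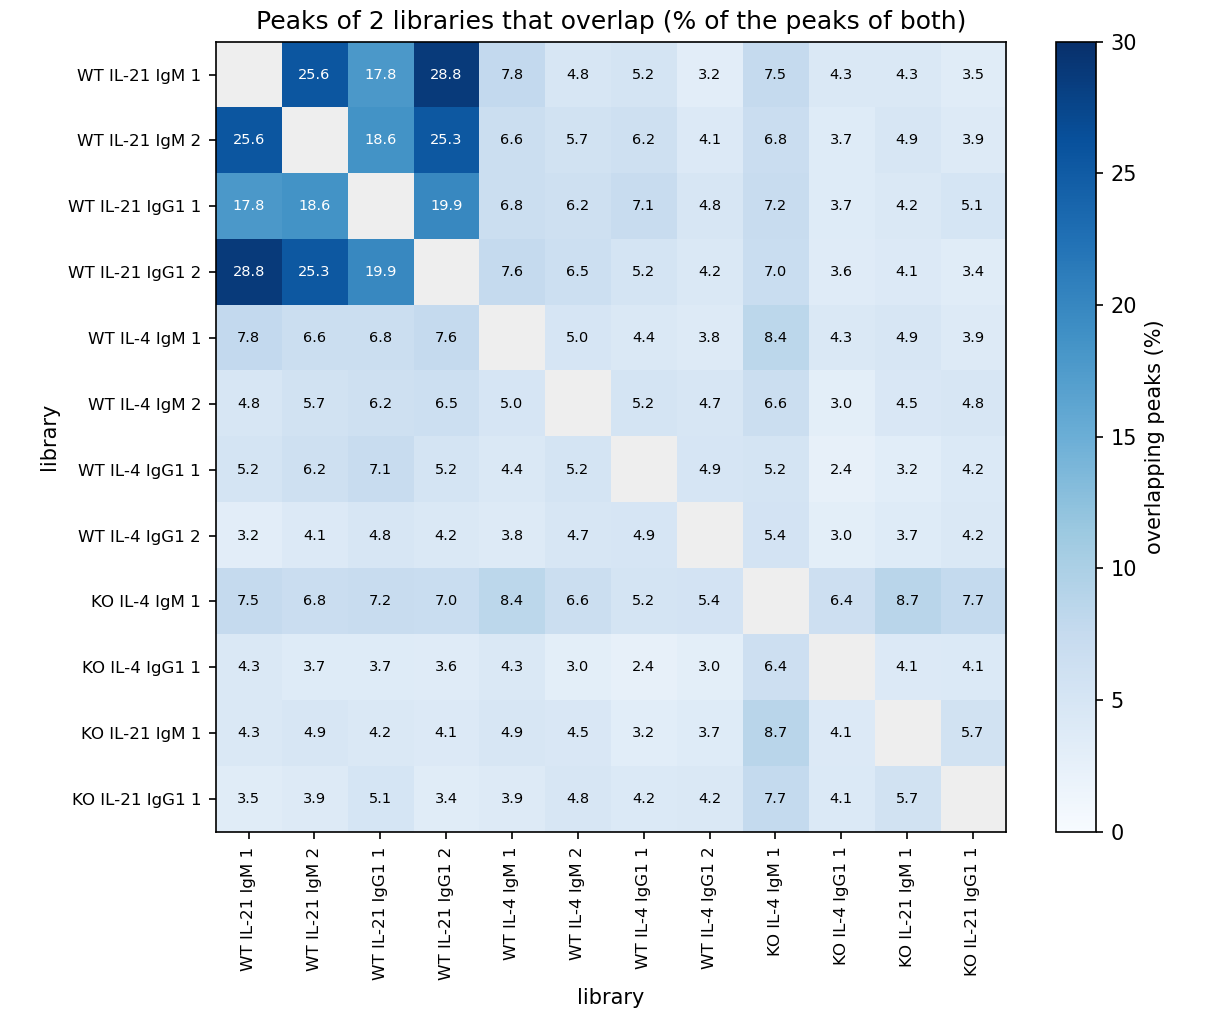
Share of the peaks of 2 libraries that overlap (colour, %) for each pair of the 12 libraries (both axes). The 6 pairs among the 4 WT IL-21 libraries reach 17.8% to 28.8%, and other pairs at most 8.71%.

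Sites gained with IL-21 lay near gene ends more often than regions found in a single library. Of the 98 regions 40 (40.8%, 95% CI 31.0 to 51.2) were within 1000 bp of either end of a protein-coding gene, against 13.4% of the 10180 regions of a single library, KO libraries included (Fisher's exact test, p = 2.64e-11). Of the 33 regions of all 4 WT IL-21 libraries with WT IL-4 peaks and no KO peak, 66.7% (95% CI 48.2 to 82.0) lay there. Nearness to gene ends was thus not particular to gained sites. The shares of the 98 and the 33 regions have overlapping intervals and were not tested against each other. By library, 28.1% of WT IL-21 peaks and 14.8% of WT IL-4 peaks lay there on average (exact permutation p = 0.0556, the smallest possible, adjusted p = 0.167). KO libraries held 11.8% to 35.4%, the highest share of any library being that of KO IgM cells with IL-4, and the difference between WT and KO did not pass (1.34 percentage points, exact permutation p = 0.802).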

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

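The tests of equal list lengths for the gained regions and for IgM against IgG1 were set before their results were seen, and the other tests in this part were chosen only after the result was seen.

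Among 18 sets of 4 libraries (6 measures in the WT IL-21, WT IL-4 and KO libraries), 2 held a library that lay far from the others, where chance alone picks out about 1 in 20 sets. The highest fold enrichment among the WT IL-21 libraries was 117 in the first IgM library, against 60.1 to 66.7 in the other 3, and it belonged to the region at Thg1l. The highest fold among the KO libraries was 26.5 in the IL-4 IgM library, against 9.36 to 10.8 in the other 3. That peak lay within Deptor (chromosome 15, 55160631 to 55160893) and was found in no other library. No explanation of these 2 values was tested.

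In KO IgG1 cells the IL-21 list was shorter than the IL-4 list (log2 difference −1.55, 648 against 1892 peaks, 1 library each), whereas in WT IgG1 cells the IL-21 lists were longer (0.83, 2 libraries each). The difference between the genotypes was not tested. Of the regions of the KO IL-4 IgG1 library 90.6% were found in no other library, and its highest fold was 9.93. The shortest WT list reached 89.98% and the KO IL-21 IgG1 list a highest fold of 9.36, so these values do not set the long list apart, and peaks near the calling limit as its cause were left open. Its lowest background of 2.02 fragments was not above that of the other KO libraries, which argues against deeper sequencing. It had a peak in 4.58% (6 of 131, 95% CI 1.70 to 9.70) of the regions found in all 4 WT IL-21 libraries and in none of the other KO libraries, which argues against a mislabelled WT IL-21 library.

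The regions gained with IL-21 in both isotypes were counted in all 35 splits of the WT libraries. Only 1, the real one, gave a count as large (98, highest of the others 8). With 35 splits the share cannot fall below 1 in 35, and the test was chosen after the count was seen. It therefore argues against chance in the grouping of the libraries but does not exclude it. With 623 peaks taken from each list 85 regions were gained, against at most 4 in the other splits, which argues against longer lists as the whole cause. A KO IL-21 library had a peak in 1.02% of the 98 regions, whereas each WT IL-21 library found 55.3% to 98.2% of the regions found by the other 3. These shares come from unlike sets, since the second also counts regions with WT IL-4 peaks. Of the 167 regions found in all 4 WT IL-21 libraries 42 had a KO peak, and such shared regions widen the contrast. Even so, the contrast argues against a signal that comes with IL-21 and does not need STAT3. Background shared by all libraries was already left out of the 98 by the absence of WT IL-4 peaks. STAT3 binding at these sites, including those at Socs3, Bcl6 and Il10, may therefore follow IL-21 in place of IL-4. This is a hypothesis found and tested on the same libraries.

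For the IgM-only (93) and IgG1-only (13) regions with IL-21, another pairing of the 4 libraries gave a larger total, 164 against 106. With 3 such splits no share under 0.05 can be had. Detection that differs between libraries whatever their isotype may explain the excess in IgM cells. With equal list lengths 58 regions were IgM only and 19 IgG1 only, a ratio of 3.05, which argues against list length as the whole cause. An isotype difference at sites such as Rnf44 and Mdm2 stays open and was not tested.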

How the results depend on the processing

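The tests chosen only after the result was seen are the background of genes with a region in at least 2 WT libraries, the gene with the nearest end, the adjustment over regions in at least 4 WT libraries and the peak numbers without the KO IL-4 IgG1 library. Of 399 alternative values of 29 results, 315 kept their direction and side of the threshold or stayed close to the reported value, 60 moved, 14 lost their call, 0 gained one and 10 reversed. The settings listed in advance for the STAT motif share (both motifs, both windows, flanking windows, thresholds, list length and replicates) were not run. Unless stated, the cause was not tested.

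Peak numbers and gene-end shares of IL-21 against IL-4 and of IgM against IgG1 kept their direction under each alternative run. The log2 difference of IL-21 against IL-4 in peak number rose to 1.82 with a −log10 q of at least 5 and 1.36 with a fold of at least 5 (exact permutation p = 0.0556 for both, the smallest possible), ran from 0.63 to 1.82 over the alternatives with all libraries, and from 0.44 to 0.91 without 1 WT replicate (exact permutation p 0.0556 to 0.333). The difference in WT peaks overlapped by KO peaks ran from −15.1 (−log10 q of at least 5) to −2.13 percentage points (equal list lengths, exact permutation p = 0.222) with all libraries, and from −2.55 to −1.75 without 1 WT replicate (exact permutation p 0.0556 to 0.111). The gene-end share of WT minus KO turned to −0.0088 percentage points with a −log10 q of at least 5 and to −0.65 with a fold of at least 5, and ran from −0.0877 to 3.21 without 1 WT replicate. The WT minus KO log2 peak number was 0.45 with a −log10 q of at least 5, 0.53 with a fold of at least 5 and 0.38 without the KO IL-4 IgG1 library (exact permutation p = 0.407, 0.383 and 0.296), and ran from −0.0587 to 0.19 without 1 WT replicate. Neither was called.

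Replicate overlap with IL-21 and IL-4 was 34.7% and 16% with a −log10 q of at least 5, 28.6% and 2.74% with a fold of at least 5, 24.7% and 7.98% with all sequences, 38.1% and 6.22% with equal list lengths, 18.8% and 3.91% with summit windows, and 17.3% and 4.08% with reciprocal overlap. Without 1 replicate the IL-21 value ran from 19.9% to 25.6%, since 1 isotype was left.

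Regions gained in both isotypes numbered 263, and lost 2, when 3 of 4 libraries sufficed, by construction of the looser rule. A replicate block gave 291 gained and 2 lost. It asked for a peak with IL-21 and not with IL-4 in at least 3 of 4 pairs, and the reverse in none. This rule is looser still by construction, since the remaining pair may have a peak with both treatments. Treatment labels exchanged within the pairs gave an exact permutation p of 0.125 for peak number. The correlations of the replicate differences of the 2 treatments were −0.0141 in IgM and 0.0064 in IgG1 cells. Most regions were found in a single library, so these values neither show nor exclude a pairing by replicate number. Without 1 WT replicate the gained count ran from 99 to 215, the lost count from 0 to 2 and the count absent in KO from 97 to 213, the highest gained counts being without the first IgG1 IL-21 library.

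A −log10 q of at least 5 gave 3 lost in IgM, and 119 gained and 0 lost in IgG1. A fold of at least 5 gave 213 gained and 1 lost in IgM, 110 gained, 0 lost and 110 absent in KO in IgG1, and 50 IgM-only and 8 IgG1-only regions. Equal list lengths gave 58 IgM-only regions. The lost count in IgG1 was 2 with all sequences, equal list lengths, summit windows or merging within 200 bp. Without regions with a KO peak, 3 were lost in IgM and 0 in IgG1. Without 1 WT replicate a side can rest on 1 library, and by construction the counts ran in IgM from 321 to 1874 gained, 10 to 1300 lost, 310 to 1847 absent in KO and 93 to 1488 IgM only, and in IgG1 from 179 to 1410 gained, 1 to 588 lost, 175 to 1398 absent in KO and 13 to 937 IgG1 only.

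For the gene lists (log2 odds ratios, Fisher's exact tests), equal list lengths ended the plasma cell call (1.48, adjusted p = 0.367) and the IL-4 and STAT6 call (2.92, adjusted p = 0.140). The rule of 3 of 4 libraries ended the survival call (2.27, adjusted p = 0.102) and the IL-4 call (2.73, adjusted p = 0.120, Fisher's exact tests). The background of genes with a region in at least 2 WT libraries ended all 5 calls: JAK-STAT 1.16, plasma cell 1.65, B cell 2.4, survival 1.85 and IL-4 3.24, with adjusted p from 0.177 to 0.376, and it turned the housekeeping value to −1.53. It drops genes that could not be gained. Without 1 WT replicate the values ran from 1.37 to 2.65 for plasma cell genes (adjusted p 0.0201 to 0.277), 1.33 to 2.94 for B cell genes (0.000908 to 0.170), 1.75 to 3.41 for IL-4 genes (0.00620 to 0.142), −1.79 to 1.81 for T and NK markers and −0.87 to 3.34 for housekeeping genes. The JAK-STAT and survival calls held without each WT replicate in turn, at 2.10 to 3.73 (adjusted p 3.44e-06 to 0.0134) and 2.00 to 3.61 (4.42e-05 to 0.0365), the lowest being without the second IgG1 and the first IgM IL-21 library. No region passed adjustment over 7461 regions or over the 208 in at least 4 WT libraries (Fisher's exact test, smallest adjusted p = 0.0606), and 98 had an unadjusted p under 0.05.

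Depth and local background limit what the absence of a peak means. The smallest pileup called anywhere in a library was 10 to 12 fragments, and more can be needed where the background is higher.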

Other observations

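The tests in the second paragraph were chosen only after the result was seen, and the values in the first are given without a test.

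Within Pvt1, a long non-coding RNA gene beside Myc, 2 regions (chromosome 15, 62168940 to 62170339 and 62181183 to 62181855) were gained with IL-21. They lay 179287 and 191103 bp from Myc, beyond the distance used to assign genes. Apart from Socs3, several gained regions were assigned to Ppp1r16b (4) and to Cradd, Fgd2 and Tha1 (3 each). These regions were chosen after their values were seen.

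Some STAT3 sites, such as those at Thg1l and Lsm4, also had a peak with IL-4. A hypothesis is that STAT3 binds such sites weakly with IL-4 and more with IL-21. The IL-4 libraries come from a parallel arm, so they do not show the state before IL-21. Of the 28 regions with a peak in at least 2 WT IL-4 libraries and in no KO library, 57.1% (16, 95% CI 37.2 to 75.5) were found in all 4 WT IL-21 libraries. Of the 112 regions with a peak in at least 2 KO libraries and at most 1 WT IL-4 library, 2.68% were (3, 95% CI 0.556 to 7.63, Fisher's exact test, two-sided p = 5.17e-11). Thg1l and Lsm4, which prompted the hypothesis, were among the 28. Without these 2 regions the share was 53.8% (14 of 26, 95% CI 33.4 to 73.4). Of the regions with a peak in at least 2 KO libraries and in no WT IL-4 library it was 1.33% (1 of 75, Fisher's exact test, two-sided p = 2.46e-09). Regions at Slc39a1, Jak3 and Stat3, seen before this test, stayed among the 26, so it was not free of values already seen. The sets also differ in genotype, so any difference between WT and KO libraries could give such shares. The first set was chosen for WT peaks and the second for few or none, and the outcome was also WT peaks. The choice thus favoured a low share in the second set, so these tests cannot decide the hypothesis. Weak STAT3 binding with IL-4 at some of the sites found with IL-21 stays a hypothesis only.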
